A study of Arabidopsis thaliana with 3 samples.

How the data were processed

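Shoots of Arabidopsis thaliana were collected at 10 days from plants grown under constant light at 22 °C, per the labels. Total RNA was purified with a Qiagen RNeasy plant kit, and 25 ng of it was copied into cDNA, amplified at one temperature with NuGEN's Ovation chemistry and labelled with biotin, per the labels' protocols. The titles give 2 Col arrays, numbered 1 and 2, and 1 flp-1/myb88 array. Nothing in the labels says whether the Col arrays came from separate plants or cultures, so p-values measure only the spread between these arrays, which may be technical.

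The deposited values were probe set intensities from RMA, per the submitters' processing notes. RMA subtracts background, normalizes the arrays against each other by quantiles and fits one value per probe set, but its software, version and settings are not given in the sources used here. The values were read as intensities on a linear scale from the numbers themselves, which ran from 6.06 to 7618 with none below 0. The test had been planned for log2 values, with log2 to be taken first if the values were linear, and this was done with no pseudocount. The 3 columns did not share one distribution, with upper quartiles of 171, 173 and 187. Because the deposited table is already summarised, signal over background and the amount of cross-hybridization per probe were not analysed here.

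The table held 22810 probe sets, of which 64 controls were kept out of the tests. Of the 22746 tested, 13513 had 1 gene in the platform annotation supplied with the values, 503 had several and 8730 had none, which leaves them unnamed here. By gene ID, 13436 probe sets matched the TAIR10.1 gene table, to 13286 different genes, and its symbols were used where they exist, without coordinates because the files name no build. Symbols from the platform annotation can be old. Each sample column was used, and 0 columns were left out.

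The comparison of the mutant with Col was fitted to all 22746 probe sets with limma (lmFit and eBayes, without trend, not robust, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual spread came from the 2 Col arrays alone (1 residual degree of freedom, 12.1 prior degrees of freedom, prior SD 0.253), and the lone mutant array was assumed to vary like Col. The median standard error of a log2 difference was 0.30, and the smallest difference called was 0.854 log2. A count with no test was set beside it, of probe sets at least 1 log2 unit (2-fold) from both Col arrays on the same side.

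On simulated data, made of 1 mutant array against 2 Col arrays at 22746 probe sets with 200 changed, the fit recovered 8% of 2-fold changes with 9 false calls, 97% of 4-fold changes with 11 and 100% of 8-fold changes with 26. With no change simulated it made 0 calls. The simulated noise was independent between probe sets, and the mutant array was given the spread of Col. A difference in quality across a whole array was therefore not covered. Where many more probe sets change, as here, the adjusted threshold is passed at smaller differences than in this simulation.

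Gene lists were fixed before the data were examined, 20 lists with 391 genes, of which 48 had a named probe set. There were 8 lists with at least 3 measured members, 10 with 1 or 2 and 2 with none. A list was described by its calls, by its calls adjusted over the list alone, and, from 3 members on, by the percentile of its median log2 difference among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile under 2.5 or over 97.5 was taken as outside. Such a percentile describes these arrays and is not a test of the genotype. Camera, with a preset correlation of 0.01 and with an estimated one, was the alternative. With 1 residual degree of freedom, the estimated correlation follows only from the direction of each member's Col difference. It is therefore poorly determined for every list, as is the p-value that rests on it.

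The genes named in the text follow a rule that was also fixed before the data were examined. It took FLP and MYB88, the 12 highest and 12 lowest log2 differences among probe sets of exactly 1 gene that were past the threshold and at least 1 log2 unit outside both Col arrays, and up to 4 members of each list with the largest distance from the nearer Col array on one side. If fewer than 5 genes passed in a direction, the places were to be filled by that distance, which was not needed. The rule gave 60 probe sets, of which 35 were past the threshold. Gene classes by annotated biotype and genome, and families with a shared symbol stem and at least 8 genes plus the tubulins, were chosen after the data were seen, and their members were named after their values were seen. A further symbol family is not reported here.

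Alternatives were an eBayes fit with an intensity trend, a robust eBayes fit, a filter at the median of the mean log2 values, cyclic loess, median centring and quantile normalization of the 3 arrays, fold limits of 1.5 and 4, each Col array left out, and each Col array taken as the lone array. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.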

Results

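Transcript levels were measured in shoots of 10-day-old Arabidopsis thaliana plants of the Col wild type and of the flp-1/myb88 double mutant. FLP and MYB88 are MYB transcription factors that limit the last division of the stomatal lineage, the cell lineage that forms the guard cells of the leaf pores. The comparison asked which transcripts differ in the mutant. There were 2 Col arrays and 1 flp-1/myb88 array, so the mutant had no replicate, and the number of arrays limits the precision of every value. After removal of control probe sets, 22746 probe sets were compared. The median intensity was 68.7 and 69.7 on the Col arrays and 64.2 on the mutant array. No probe set named as FLP or MYB88 was among those analysed here, so neither mutated gene could be used to check the label of the mutant array.

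The mutant array differed widely from both Col arrays. With limma, 2700 probe sets were higher and 3282 were lower in the mutant at a Benjamini-Hochberg adjusted p under 0.05, which is 26.3% of those tested. By size alone, 1166 probe sets were at least 2-fold above both Col arrays and 2200 were at least 2-fold below both. The Col arrays differed from each other by at least 2-fold at 451 probe sets, against 4028 between the mutant and Col replicate 1 and 6152 between the mutant and Col replicate 2. Across probe sets, which are not independent replicates, log2 values correlated at r = 0.974 between the Col arrays, 0.911 between the mutant and Col replicate 1 and 0.872 between the mutant and Col replicate 2. The mutant value lay outside both Col values at 86.7% of probe sets, where 3 like arrays would give 66.7%. The median difference of all probe sets was 0.10 log2 as deposited and 0.21 after median centring of the arrays. That centring turned the balance of calls from 54.9% lower to 44.8% lower, and that of the 2-fold counts from 65.4% lower to 52.8% lower, at 1697 higher and 1902 lower. Quantile normalization left 1749 higher and 2376 lower calls, 18.1% of probe sets. Without Col replicate 1 the counts at least 2-fold from the remaining Col array were 2665 higher and 3487 lower, and without Col replicate 2 they were 1405 and 2623, as values with no test.

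**Figure D1:**
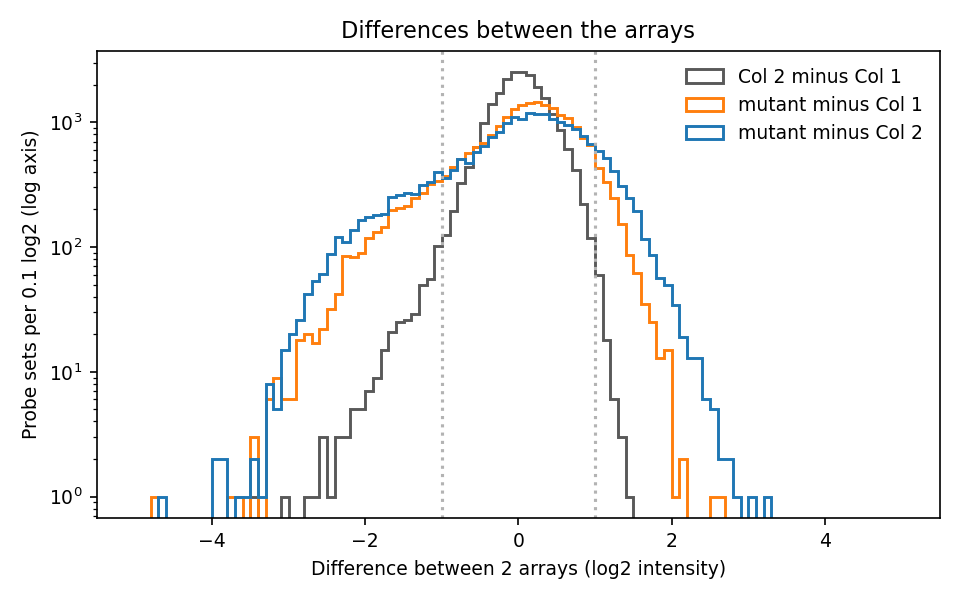
Histograms of the difference in log2 intensity between each pair of arrays over 22746 probe sets (x axis, log2 units; y axis, probe sets per 0.1 log2 on a log scale), with dotted lines at a 2-fold difference. The Col arrays differ by at least 2-fold at 451 probe sets and the mutant differs at 4028 and 6152, with a longer tail on the lower side.

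Signs of RNA quality and amplification moved with the mutant array, and so with every gene group described here. The 3′ probe set exceeded the 5′ probe set by more on the mutant array than on both Col arrays in 6 of 6 pairs of control probe sets. For the second actin pair this log2 difference was 3.45 and 3.17 in Col and 5.15 in the mutant, and for the second GAPDH pair 0.74 and 0.55 against 1.66. The Col arrays were also ordered along the mutant difference. Across probe sets, which are not independent replicates, the difference of the mutant from the Col mean correlated with the difference of Col replicate 2 from Col replicate 1 at r = -0.385 (Spearman's rho = -0.443). Called rises had a median Col difference of -0.22 log2 and called falls one of 0.36.

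**Figure D2:**
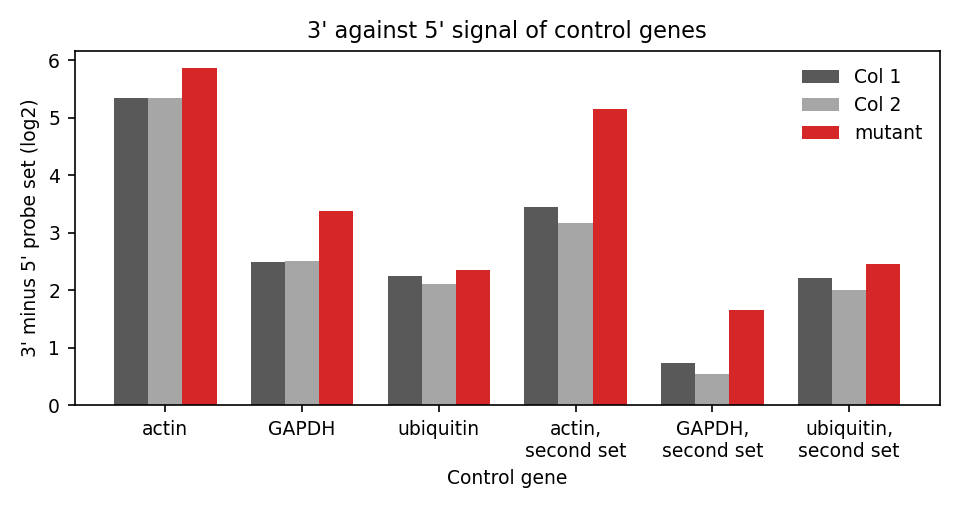
Log2 intensity of the 3′ probe set minus that of the 5′ probe set for 6 pairs of control probe sets (x axis), with 1 bar per array (y axis, log2 units, starting at 0). The mutant bar is the highest in all 6 pairs, with the widest gap at the second actin pair, 5.15 against 3.45 and 3.17.

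Among genes that rose, ATC led with a log2 difference of 2.56 ± 0.30 (SE; limma adjusted p = 0.000389), or 5.89-fold. ATC is a relative of the flowering repressor TFL1. EXPA4, which encodes an expansin of the cell wall, rose by 2.38 ± 0.35 log2 (limma adjusted p = 0.000766). GSTU20, a glutathione transferase, rose by 2.08 ± 0.37 log2. The other 9 of the 12 largest rises were at loci without a symbol in the gene table. They ran from 1.96 at AT5G45620 to 2.40 at AT1G71730, where the Col arrays themselves differed, at 5.75 and 4.55 against 7.55 in the mutant. They also took in AT4G02720, AT5G64190, AT3G08920, AT3G15680, AT3G01340, AT2G37190 and AT4G28240. At each of the 12 largest rises, EXPA4 and GSTU20 among them, Col replicate 2 lay below Col replicate 1. The gap was widest at AT1G71730, followed by GSTU20, AT4G02720, AT3G15680 and EXPA4, and narrowest at ATC. This is the same direction as the median Col difference of all called rises, and the size of each rise depends on the Col array used.

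Falls reached further than rises. The probe set of AT3G44470 fell by 3.57 ± 0.34 log2, or 11.9-fold (limma adjusted p = 0.000255), and AT3G42090 fell by 3.50. AT1G72920, which encodes a protein with a TIR domain of the kind found in plant immune receptors, fell by 3.45 ± 0.30 log2 (limma adjusted p = 0.000165), from 9.68 and 9.76 on the Col arrays to 6.26. VPS24.2, a subunit of the ESCRT machinery that sorts membrane proteins, fell by 3.01. The remaining 8 of the 12 largest falls were AT2G04210, AT3G12840, AT3G30200, AT2G25990, AT5G19240, AT3G53550, AT4G04820 and AT2G30810, with log2 differences from -3.07 to -2.87. Col replicate 2 lay below Col replicate 1 at AT3G12840, AT5G19240 and AT4G04820, and above it at the others of the 12. The Col values were 7.95 and 8.66 at AT3G44470, and 7.61 and 8.53 at AT2G30810. The size of these falls also depends on the Col array used. Of these 12, the probe sets of AT3G44470 and AT2G04210 are of the _s_at type, which can match several genes, and those of AT2G25990 and AT4G04820 of the _x_at type, which can cross-hybridize, so these falls may not belong to the named locus alone. All 126 _x_at probe sets had a median difference of -1.41 log2, with 77 lower and 0 higher. AT3G44470, AT3G42090, AT2G04210 and AT4G04820 are annotated as pseudogenes. Of all 989 pseudogenes measured, a class chosen after the data were seen, 230 were lower and 18 were higher at limma's threshold.

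Of the stomatal lineage regulators, MUTE was higher in the mutant. MUTE, the basic helix-loop-helix factor that turns a meristemoid into a guard mother cell, rose by 1.07 ± 0.31 log2 (limma adjusted p = 0.0247), from 3.80 and 4.21 on the Col arrays to 5.08, below the array median. It was the single member past the threshold among the 5 of 24 list genes that had a named probe set, both over all probe sets and adjusted over the list alone. The bacterial poly-A control probe sets, which had low values, were also higher on the mutant array, at a median log2 of 3.47 against 3.10 and 3.04. How far such a shift at low values adds to the rise of MUTE was not tested. STOMAGEN, a secreted peptide that promotes stomatal formation, differed by 0.47 ± 0.30 log2 (limma adjusted p = 0.270). SPCH, which starts the lineage, differed by -0.35 and FAMA, which completes guard cell formation, by -0.17, neither past the threshold. The median difference of the list lay at percentile 49.2 of random lists matched on expression, and its sign depended on the Col array left out (0.31 without replicate 1 and -0.16 without replicate 2).

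Guard cell genes moved in both directions, with 3 of the 4 measured members lower and 1 higher, over all probe sets and adjusted over the list alone. GC1 (AT1G22690), known for a promoter active mainly in guard cells, fell by 1.22 ± 0.30 log2, or 2.32-fold (limma adjusted p = 0.0108), from 10.07 on both Col arrays to 8.85. BLUS1 (AT4G14480), a kinase of blue light signalling in guard cells, fell by 0.98 (limma adjusted p = 0.0293), a call lost after quantile normalization, at -0.89 and an adjusted p of 0.0614. CHX20, a guard cell cation exchanger, fell by 0.91 (limma adjusted p = 0.0404). PATROL1 (AT5G06970), which carries a proton pump to the plasma membrane, rose by 0.90 (limma adjusted p = 0.0419), and this call was lost after cyclic loess, at 0.65 and an adjusted p of 0.124, and after quantile normalization, at 0.73 and an adjusted p of 0.108. CHX20 lost its call after median centring, at -0.81 and an adjusted p of 0.0671. The list median of -0.95 lay at percentile 2.49 of random lists, just outside the limit of 2.5 but within the error of the random draws. Without Col replicate 1 it lay at 4.1, and limma's camera gave p = 0.153 with a preset correlation and p = 0.384 with an estimated correlation. These 4 are of 31 genes on the list, so most guard cell genes were not analysed here.

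**Figure D3:**
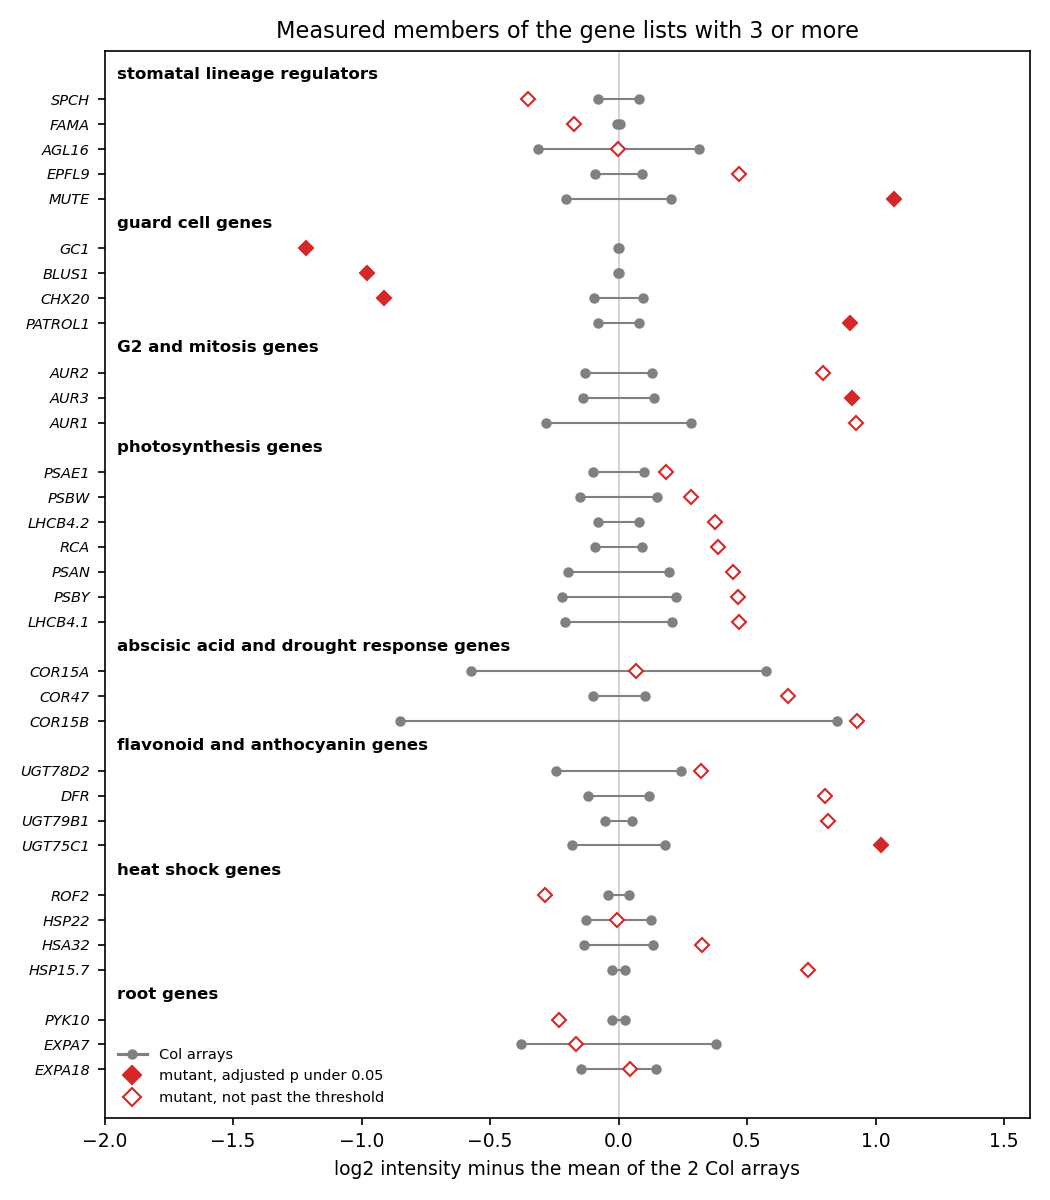
Log2 intensity of each measured member of the gene lists with at least 3 measured members, minus the mean of the 2 Col arrays (x axis, log2 units). Grey points joined by a line are the Col arrays and red diamonds the mutant array, filled where limma's adjusted p was under 0.05. GC1 lies at -1.22 and MUTE at 1.07, and each of the 7 photosynthesis genes lies above both Col arrays without passing the threshold.

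Of 3 measured Aurora kinase genes, 1 rose in the mutant over all probe sets and 3 did so adjusted over the list alone. All 3 measured members of the G2 and mitosis list, out of 29, encode these kinases of the mitotic spindle and the division plane. AUR3 rose by 0.91 ± 0.31 log2 (limma adjusted p = 0.0428), from 4.21 and 4.49 on the Col arrays to 5.26. Its Col values, like those of MUTE, lay near the Col medians of pseudogenes (4.06 and 3.99), so neither gene was shown to be above background in Col and the sizes of both changes are uncertain. AUR1 differed by 0.92 (adjusted p = 0.0529) and AUR2 by 0.79 (adjusted p = 0.0697) in the same limma fit. The list median of 0.91 lay at percentile 95.5 of random lists, inside the upper limit, at 98.9, outside it, without Col replicate 2, and at 89.5 without Col replicate 1. Camera gave p = 0.042 with a preset correlation (adjusted p = 0.168 over 8 lists) and p = 0.288 with an estimated correlation. Of the G1 and S phase list, 2 of 34 genes were measured and none passed over all probe sets, while 1 passed adjusted over the list alone. That gene, MCM7 (PRL), a subunit of the replicative helicase, differed by 0.87 ± 0.31 log2 (limma adjusted p = 0.0506). Its Col values of 4.27 and 3.98 also lay near the pseudogene medians. MCM7 was therefore not shown to be above background in Col either, and the size of its change is uncertain. The low-valued bacterial poly-A controls were also higher on the mutant array, at a median log2 of 3.47 against 3.10 and 3.04 in Col. How far such a shift adds to the differences of AUR1, AUR3 and MCM7 was not tested.

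Of 4 measured flavonoid and anthocyanin genes, 1 rose over all probe sets. UGT75C1 (AT4G14090), an anthocyanin glucosyltransferase, rose by 1.02 ± 0.31 log2, or 2.03-fold (limma adjusted p = 0.0288). It lost its call after quantile normalization, at 1.03 and an adjusted p of 0.0552. UGT79B1 (UF3GT), which adds xylose to anthocyanins, differed by 0.82 (limma adjusted p = 0.0597). DFR, the reductase at the entry to anthocyanins, differed by 0.80 (limma adjusted p = 0.0661), and UGT78D2 by 0.32. Adjusted over the list alone, 3 of the 4 measured members of 19 were higher and none was lower. Each of the 4 lay above both Col arrays, and the list median of 0.81 was at percentile 93.7. Camera gave p = 0.0417 with a preset correlation (adjusted p = 0.168 over 8 lists) and p = 0.490 with an estimated correlation.

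Single members of other lists also passed the threshold. STZ (ZAT10), a zinc finger repressor induced by cold and handling, fell by 2.34 ± 0.32 log2, or 5.05-fold (limma adjusted p = 0.000543). It was 1 of 2 measured members of its list. TRY, a small MYB protein that keeps trichomes apart, fell by 1.84 ± 0.30 log2, or 3.58-fold (limma adjusted p = 0.00123), the one measured trichome gene. GH3.3, which conjugates auxin to amino acids, rose by 1.30 ± 0.30 log2, or 2.46-fold (limma adjusted p = 0.00786). IAA29, the other auxin gene measured, differed by 0.11. WSD1, a wax ester synthase and the one cuticle gene measured, fell by 1.09 ± 0.35 log2 (limma adjusted p = 0.0352), with a call lost after median centring, at -0.99 and an adjusted p of 0.0639, and after quantile normalization, at -0.93 and an adjusted p of 0.114. The WSD1 difference was -0.72 without Col replicate 2 and -1.47 without Col replicate 1. In these lists of single calls the counts adjusted over the list alone were the same as those over all probe sets.

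In the remaining lists no measured member passed limma's threshold, over all probe sets or adjusted over the list alone. All 7 measured photosynthesis genes of 34 lay above both Col arrays, with a median difference of 0.39 at percentile 78.9, which was 0.25 without Col replicate 2. LHCB4.1, a light-harvesting protein, differed by 0.47, PSAN of photosystem I by 0.44 and RCA, the activase of Rubisco, by 0.39. Of the abscisic acid and drought genes, 3 of 30 were measured. COR47 differed by 0.66 and COR15B by 0.93, but the list's median difference between the Col arrays was -1.15. The list median of 0.66 was 0.0796 without Col replicate 2. Heat shock genes (4 of 15 measured) had a median of 0.16 at percentile 55.7, which was 0.0290 without Col replicate 1 and 0.29 without Col replicate 2, with HSP15.7 at 0.74 and ROF2 at -0.29. Root genes (3 of 12 measured) had a median of -0.17 at percentile 17.0, with PYK10 at -0.23, and without Col replicate 1 the median was 0.19 at percentile 57.9. The glucosinolate gene BCAT4 differed by 0.75 (limma adjusted p = 0.0903) and UGT74B1 by 0.13. SAG101 of the salicylic acid list differed by -0.21, PDF1.2 of the jasmonate list by -0.13, CLV3 of the shoot apex list by -0.12, and the one measured clock gene by 0.03. The 13 vascular genes were not analysed here.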

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

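The tests of explanations in this part were chosen after the results were seen.

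Some control probe sets, which entered none of the comparisons, set the mutant array apart from both Col arrays. The second actin pair had a 3′ minus 5′ log2 difference of 5.15 on the mutant array against 3.45 and 3.17 on the Col arrays, and the difference was larger on the mutant array in 6 of 6 control pairs. The bacterial poly-A control probe sets had a median log2 value of 3.47 on the mutant array against 3.10 and 3.04, with the mutant above both Col arrays at all 27. The hybridization controls showed no such rise, with medians of 10.87 and 11.17 in Col and 10.81 in the mutant, which lay above both Col arrays at 2 of 18.

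Probe sets lower in the second than in the first Col array tended to be higher in the mutant. The covariance of the 2 differences across probe sets was -0.13. Noise in the Col arrays that is independent between probe sets can give at most 0.0833 in size. Such noise is therefore argued against as the whole source. The standard error of 0.00265 takes probe sets as independent replicates, which they are not, so it may be too small. Error shared by many probe sets of one array was not covered. RNA quality or amplification graded across the 3 arrays stays open: the 3′ minus 5′ difference was ordered Col replicate 2, Col replicate 1, mutant in 5 of 6 control pairs, but the mutant's place was already known, the Col arrays nearly tied in the first actin pair (5.34 and 5.35), and the pairs are of 3 genes, too few to decide. The relation covers 14.9% of the variance of the mutant difference, and a graded biological state of the plants was not tested and stays open. With 1 mutant array, genotype and the handling of that sample are not separated by the design.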

How the results depend on the processing

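Of the alternative values that answer a comparison, 62 kept their side of the threshold or stayed close, 14 counts moved by over 1.5 times, 4 list values lost a call (all of the guard cell list) and 3 gained one. For single genes, classes and families 522 were kept, 9 calls were lost and 21 gained, without counting named genes with a Col array left out, where the rule that chose them fixes the direction and no test was run. No value past its threshold or outside its limits changed sign, while some that were not did. Cyclic loess and median centring gave 2211 and 3288 higher and 3555 and 2670 lower calls, and of the 5982 main calls 5296 and 5364 were shared. Quantile normalization gave 1749 higher calls. The filter on low values gave 2117 higher and 1976 lower calls among 11373 probe sets. That turned the balance of calls from 54.9% lower to 48.3% lower, and the cause was not tested. Each Col array as the lone array gave 0 higher and 0 lower calls with limma (95 and 152 at an unadjusted p under 0.05), since the mutant then adds to the spread. At least 1.5-fold from both Col arrays were 4247 higher and 3887 lower, at least 4-fold 4 and 309, and with the filter 638 and 1287. Without each Col array in turn the 2-fold counts ran from 1405 to 2665 higher and from 2623 to 3487 lower, since 1 array then sets the limit. The guard cell median was -1.11 after cyclic loess (percentile 2.51, within the error of the random draws), ran from -0.996 to -0.90 without each Col array, and had camera p of 0.153 and 0.384. The G2 and mitosis median ran from 0.77 to 1.05 without each Col array, and camera with a preset correlation gave p = 0.042 there and 0.0417 for the flavonoid list, against p = 0.288 and 0.490 with an estimated correlation and an adjusted preset p of 0.168 for both, where the causes of the changed calls were not tested.

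Of the 60 named probe sets, quantile normalization ended 4 calls and made 1, median centring ended 2 and made 4, and cyclic loess ended 1 and made 2, while the intensity trend made 2 and the filter made 4. The LCR family, chosen after the data were seen, lay at percentiles 6.62 and 5.43 without each Col array. No paired analysis was possible because the mutant has 1 array. Not run were limma counts without a Col array (no residual degrees of freedom), the mean over probe sets of a gene (no list gene has several), the filter where it left under 3 members, and the alternatives for the mutated genes. The arrays' signal over background was not analysed here.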

Other observations

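Gene families with a shared symbol stem, the gene classes and all tests of explanations in this part were chosen after the data were seen. Of 33 families, 6 had a median outside the percentile limits. Tubulin genes, which build the microtubules, were higher: 4 of 7 measured rose and none fell, the median difference was 1.17 log2 at percentile 99.98 of matched random lists, and it ran from 0.98 to 1.28 over the other normalizations. TUB9 rose by 1.44 ± 0.31 log2 (limma adjusted p = 0.00591), TUB6 by 1.33 and TUA6 by 1.17, TUA1 rose too, and TUB1, at 0.46, was not past the threshold. Tubulin genes had a median Col difference of -0.17 log2, of the same sign as that of all called rises. It lay at percentile 15.9 of matched random lists, inside the limits.

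Genes of the SWEET family were lower. SWEET genes encode sugar transporters, and 10 of 14 fell and none rose, with a median of -1.11 at percentile 0.10. SWEET6 fell by 2.24 and SWEET2 had a difference of -1.94, while SWEET11 differed by 0.57 without passing the threshold. The median stayed negative under the other normalizations. Col replicate 2 exceeded Col replicate 1 by a median of 0.37 log2, at percentile 99.5 of matched random lists, outside the limits. Organelle genes were lower too. Of 8 mitochondrial nad genes, subunits of respiratory complex I, 3 fell, with nad1 at -1.64, nad4L at -1.25 and nad5 at -1.02. Of the 8 RPS genes 7 fell, and their median Col difference was 0.27 log2 at percentile 99.7. These 8 RPS genes are plastid-encoded and are counted again among the 69 plastid-encoded genes below, so the 2 results are not separate. Of 8 LCR genes, which encode small cysteine-rich peptides, 4 fell and the median was -0.63 at percentile 2.46, but at 6.62 and 5.43, inside the limits, without Col replicate 1 and without Col replicate 2.

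Pseudogenes and plastid-encoded genes were lower in the mutant, at 230 of 989 and 42 of 69, and all 69 plastid genes lay below both Col arrays (rbcL -1.33, rpoB -1.94), with a median Col replicate 2 minus Col replicate 1 of 0.30 log2 at percentile 100, while the 12224 nuclear protein-coding genes had 1475 rises and 1756 falls. The pseudogene median still differed by -0.19 log2 from that of matched random lists in the normalization that brought it nearest. Scaling that shifts genes of like expression alike moves both medians, so this gap was nearly sure to outlast another normalization. It shows that pseudogenes fell beyond genes of like expression, but scaling was hardly tested by it. For plastid-encoded genes the gap under the other normalizations is not reported here. Genomic DNA in the Col RNA stays open: the lower quartile of pseudogenes exceeded the bacterial control median by at least 0.281 log2 more in Col than in the mutant, but only because that control median was higher in the mutant, and the quartile itself was not lower there (3.44 and 3.37 in Col, 3.52 in the mutant). The upper quartile of pseudogenes was lower in the mutant, at 4.66 against 5.45 and 5.52 in Col. Stronger 3′ bias in the mutant array, seen in 6 of 6 control pairs, cannot be told apart from the genotype because the mutant has 1 array. A change of these transcripts by the genotype was not tested and stays open.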
